A study of Bacillus subtilis with 4 samples.

How the data were processed

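Transcript levels of a Bacillus subtilis strain with the G1122D substitution in RpoC were measured against the wild type on 4 dual-colour arrays. Per the labels' protocols, total RNA was purified with a column kit, treated with DNase, reverse transcribed and labelled indirectly with Alexa Fluor 555 or 647. The deposited table holds log2 ratios, and per the labels each ratio is the mutant value divided by the wild-type value, on swapped arrays as well. Scanner, background subtraction, normalization, centring and averaging of spots are not given in the sources used here. That the values are on the log2 scale was read from the values: of 1412 values that would be ratios of 3 to 20 in base 2, 30.7% were multiples of 0.5 within rounding of the fourth decimal, against 0.154% by chance, and 0.0585% in base e. Of 4116 rows, 10 were control probes and were left out of all tests.

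The table held 0 negative values. Between 37.3% and 61.0% of genes had a value on an array. The median of the listed values was 1.13 and 1.07 on the forward arrays and 0.55 and 0.51 on the swapped arrays; over all genes, with blanks ranked lowest, it was 0.16 and 0.22 on the forward arrays and lay among the blanks on the swapped ones. Blanks were treated as values that were either below 0 or not recorded. This affects the measurements in 3 ways: falls cannot be quantified, a mean exists only for genes listed on every array, and ratios of weak spots can be very large, since a small denominator sets them.

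Arrays of the same RNA were averaged first and the 2 pair means were tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3. The 565 genes with 4 values were fitted, all other genes entered the Benjamini-Hochberg adjustment with a p of 1 over 4106 genes, and a call needed an adjusted p under 0.05 and a 2-fold change. The replicates are separate RNA pairs per the labels. Whether they came from separate cultures is not stated for these 2, so limma's p-values measure the spread between these pairs. The exact tests of gene lists count genes as if they were independent and measure no spread between pairs, so their p-values can be too small. A camera test of gene lists had been fixed as the main test before the data were examined. Because blanks are not values, it was replaced by Fisher's exact test (scipy 1.17.1, two-sided) of 2 outcomes per list, a value on all 4 arrays and a value on none, against all other genes, adjusted over the 68 tests of 34 lists. Camera (preset correlation 0.01, estimated correlation, ranks) and fry were run with blanks set to 0 as alternatives. An estimate of the correlation from 2 pair means leaves camera almost no power, so a loss in that setting decides nothing. The lists were fixed before the data were examined; 885 of their 886 entries were found on the array, 801 by name and the others through a table of 80 older names written afterwards without regard to values. Of the 4106 genes, 3036 matched a symbol of the RefSeq annotation of assembly ASM904v1, and 3111 could be placed in its gene order with the older names. No coordinates are given, since the build behind the array is not stated.

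Named genes followed a rule fixed beforehand: up to 15 genes with the largest changes among those passing, or, where fewer than 10 passed, the 10 largest means among genes with the same sign on all arrays; up to 4 members with the largest means of each list passing its test and up to 2 of other lists; and 13 genes of the transcription machinery and cell wall in any case. As fixed, the rule meant lists passing camera. Lists with an excess in the exact test that replaced camera, on all 4 arrays or on none, were used in their place. Genes named outside this rule were chosen after their values were seen, as were rocA and the genes of the closing section. Alternatives were other scalings, blocks, orientations, thresholds, list tests and each pair alone. Centring on the median was not run, because the median of a swapped array lies among its blanks. An added alternative, chosen after seeing the data, instead lowered each array until the same number of genes was listed, by 0.58 and 0.68 on the forward arrays.

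The steps were tested on simulated data for this comparison, 4106 genes with negatives blanked and 200 changed genes. Gene-wise spreads were drawn from limma's prior, and a dye effect of chosen size, opposite in sign on forward and swapped arrays, was added. Of 50 genes raised 4-fold limma called 15, and of 50 raised 8-fold it called 39. Of 50 raised 2-fold it called 0, and of 3906 unchanged genes 2. These shares do not carry over to the data. There pbpE, at a mean log2 ratio of 2.36 ± 0.02, had a limma p of 0.00163, and rocA, at 3.15 ± 0.30, had 0.00141. Both adjusted to 0.452. At least 2-fold on all arrays were 27 of the 4-fold and 45 of the 8-fold genes, and 4 of the unchanged genes. Among the 128 unchanged genes listed on all arrays the mean log2 ratio was 0.73, since blanking removes the lower values; the simulated spreads set this value. The rank product called 0 genes in the simulation. Of 50 genes lowered to 0.25 of the wild type, 43 had no value on any array, as had 157 unchanged genes. A list of 50 with 30 raised genes was called, and 0 of 20 unchanged lists were. The unchanged lists were random draws from genes simulated independently, so they do not test lists that hold whole operons. Figures were drawn with matplotlib 3.10.9.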

Results

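RNA from a Bacillus subtilis W168 strain carrying the G1122D substitution in RpoC, the β′ subunit of RNA polymerase, was hybridised against RNA from the wild type, both grown in LB broth to an OD600 of 0.4. The data are 4 dual-colour arrays made from 2 RNA pairs, each hybridised forward (wild type in Alexa Fluor 555, mutant in Alexa Fluor 647) and dye-swapped. Per the labels ratios are mutant over wild type on every array, and the 2 arrays of a pair count as 1 replicate, so n = 2. The labels speak of 3 independent RNA preparations; 2 pairs were analysed here. Of 4106 genes, 2312 and 2505 had a value on the forward arrays of pairs 1 and 2, and 1548 and 1533 on the swapped arrays. No value lay below 0 on the log2 scale: a blank stands for a ratio below 1 or for a spot with no record, and the table does not separate them. A higher transcript level in the mutant could therefore be measured, and a lower one could not. A mean needs 4 listed values and is thus never below 0: simulated unchanged genes listed on all 4 arrays had a mean log2 ratio of 0.73. In the simulation 128 of 3906 unchanged genes were listed on all 4 arrays, against 565 of 4106 genes in the data. The 0.73 therefore shows the direction of this bias and is no threshold for a single gene. The number of arrays limits the precision of every value.

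**Figure D1:**
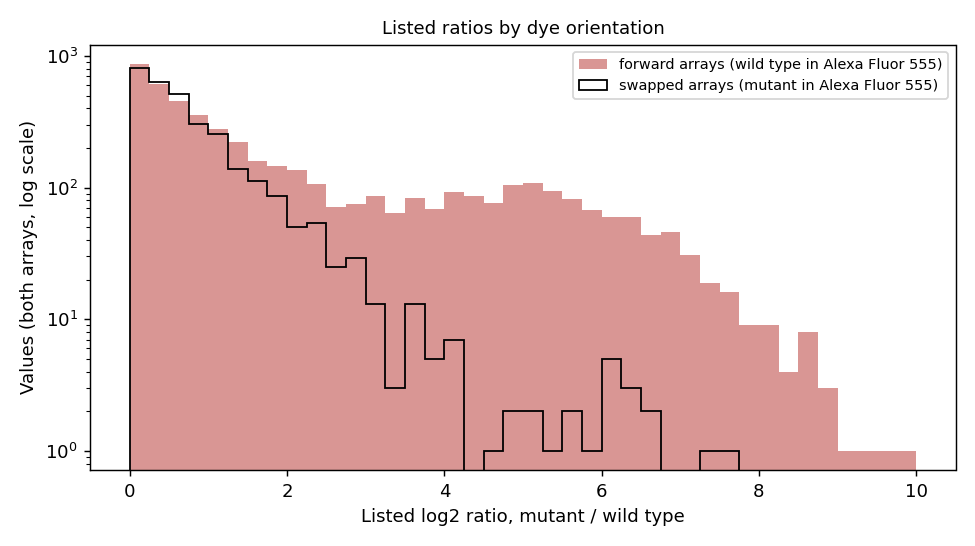
Histogram of the listed log2 ratios (mutant over wild type, x axis) on the 2 forward arrays (filled) and the 2 swapped arrays (line), with the number of values on a log scale. Forward values reach 9.84 and swapped values 7.57, and no value lies below 0.

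The comparison asks which transcripts differ when RNA polymerase carries the altered β′ subunit. A set of 87 genes had a ratio of at least 2-fold, mutant over wild type, on all 4 arrays. Among them were rocA (arginine catabolism) with a mean log2 ratio of 3.15 ± 0.30, racX (an amino acid racemase) with 2.89 ± 0.54, pbpE (penicillin-binding protein 4*) with 2.36 ± 0.02 and ywaC (a (p)ppGpp synthetase) with 2.32 ± 0.14 (SD over n = 2 RNA pairs). The 87 genes became 41 when the arrays were brought to the same number of listed genes, which lowers the forward arrays by 0.58 and 0.68, an alternative chosen after seeing the data. Pair 1 alone gave 222 such genes and pair 2 gave 216, so that 11.7 shared genes were expected by chance (Fisher's exact test, two-sided, p = 5.11e-59). Both pairs hold the same dye orientations, and a dye effect shared by them raises that overlap. Between orientations, 825 genes were at least 2-fold on both forward arrays and 174 on both swapped arrays, with 35.0 shared genes expected by chance (Fisher's exact test, two-sided, p = 1.72e-19). Both orientations hold the same RNA, so a difference particular to an RNA pair raises the overlap between orientations. Genes on one chromosome are not independent, which makes both p too small. The 10 largest means among genes with a log2 value above 0 on every array belonged to yflA (5.33 ± 1.08), ykgA (5.15 ± 0.28), yscB (4.95 ± 0.01), yfhL (4.70 ± 1.96), yvfC (4.52 ± 2.25), yfmA (4.21 ± 3.92), ykoL (4.19 ± 0.20), ylqB (4.09 ± 0.77), yxbG (3.96 ± 2.75) and yrzF (3.88 ± 1.01). Each of these genes had a forward value above 5, and a weak denominator can make such a ratio very large. The ranking may therefore reflect weak spots. The arrays behind such a mean could lie far apart: yscB stood at 8.30 and 8.67 on the forward arrays and at 1.61 and 1.21 on the swapped ones. The gene yrzF was at 0.08 on the swapped array of pair 1 and at 6.27 on the forward one.

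No single gene passed the gene-wise test. limma on the pair means called 0 genes, with a smallest adjusted p of 0.452, and a rank product called 0 with a smallest adjusted p of 0.0717. The gene yscB, at 4.95 ± 0.01, had a limma p of 0.000237, which also adjusted to 0.452. The 0 calls are therefore no evidence against large changes in single genes. At an unadjusted p under 0.05 limma had 293 of the 565 fitted genes and the rank product 329 genes. Only genes without a value below 0 could be fitted, so every mean is at or above 0 by selection. The 293, and counts adjusted over a list alone, are therefore inflated. With the 4 arrays taken as separate samples limma called 46 genes, and 72 with the RNA pair as a random block, where the estimated correlation within a pair was -0.0314.

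Genes of SigW, the sigma factor of the response to cell envelope stress and antimicrobial compounds, were listed on all 4 arrays, at a ratio of 1 or more, more often than other genes. Of 51 members on the array, 38 (74.5%) had a value on all 4 arrays, against 13.8% of all genes (Fisher's exact test, two-sided, adjusted p = 1.72e-21), and no member lacked a value everywhere. A competitive test (camera) with blanks at 0 gave an adjusted p = 0.0458 with a preset correlation and 0.710 with an estimated correlation. The latter is estimated from 2 pair means and kept no list in either direction, so this loss does not set SigW apart. The members with the largest means were yfhL (4.70 ± 1.96), racX (2.89 ± 0.54), pbpE (2.36 ± 0.02) and yobJ (2.28 ± 0.71), and 9 members were at least 2-fold on all 4 arrays. The member median, with blanks ranked lowest, was 1.69 and 1.72 on the arrays of pair 1 and 0.48 and 0.60 on those of pair 2. The sigW gene had values of 0.45 and 0.46 in pair 1 and none in pair 2. Members past limma's threshold numbered 0 over all genes and 0 adjusted over the list alone.

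Genes of SigB, the general stress sigma factor, were likewise listed on all 4 arrays more often than other genes. A value was listed on all 4 arrays for 42 of 56 members (75%; Fisher's exact test, adjusted p = 1.03e-23), and 12 were at least 2-fold on each. Camera with an estimated correlation, which kept no list, gave an adjusted p = 0.654. The leading members were ykgA (5.15 ± 0.28), ydaT (3.81 ± 1.54), yflT (3.65 ± 1.33) and yoaA (2.86 ± 2.09), and yoaA was at 0.03 and 0.43 on the swapped arrays. The sigB gene itself had a mean of 0.89 ± 0.04. Simulated unchanged genes that were listed on all 4 arrays averaged 0.73, which is no threshold for a single gene. Member medians were 1.01 and 0.87 in pair 1 and 1.73 and 1.59 in pair 2. No member passed limma over all genes. Adjusted over the list alone 22 passed, a count inflated because fitted values are never negative. The gene yceD is a member of both the SigB and the SigW list.

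**Figure D2:**
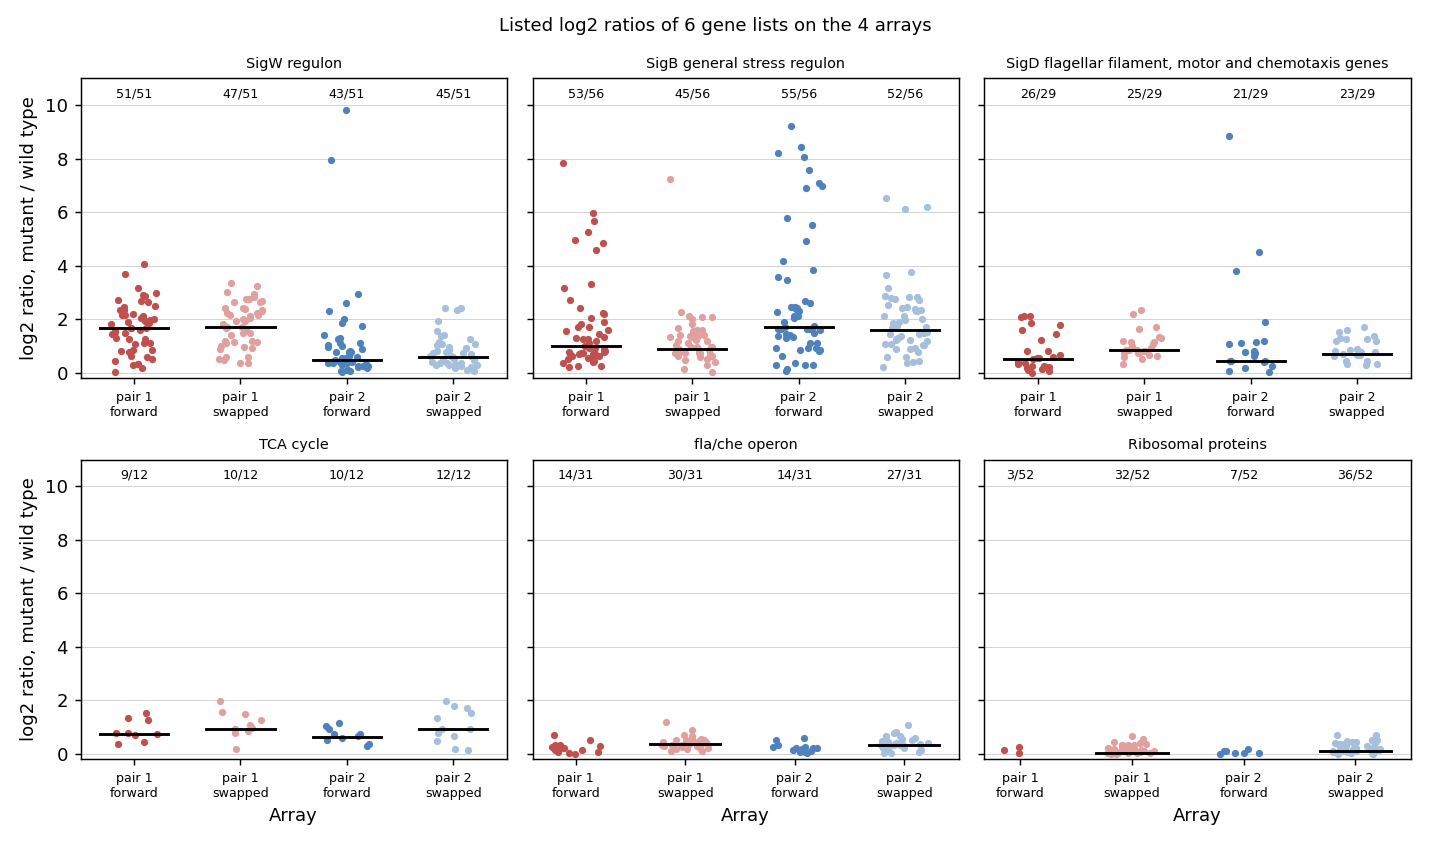
Listed log2 ratios (y axis) of the members of 6 gene lists on each of the 4 arrays (x axis). Each point is a gene, bars are medians over all members with blanks ranked lowest (drawn where the median member is listed), and the numbers above give listed over all members. The SigW medians are 1.69 and 1.72 in pair 1 and 0.48 and 0.60 in pair 2, while those of SigB are higher in pair 2.

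Genes read by SigD, the sigma factor of motility, were the next group. Of 29 genes of the flagellar filament, motor and chemotaxis list, 17 (58.6%) had a value on all 4 arrays (Fisher's exact test, adjusted p = 3.21e-07). With an estimated correlation, a setting that kept no list, the adjusted p was 0.650 (camera). The largest means were those of degR (3.21 ± 2.70), lytA (1.99 ± 0.35), lytB (1.71 ± 0.42) and lytC (1.44 ± 0.18); the lyt genes encode the major autolysin LytC and its operon partners, not motility proteins. The separate list of cell division and autolysin genes had 2 of 18 on all 4 arrays (adjusted p = 1 by the exact test). A single forward array, at 8.85, dominates the mean of degR. Of the SigD list, 4 genes were at least 2-fold on all 4 arrays: lytA, lytB, lytC and ywtD (pgdS). None of these is a filament, motor or chemotaxis gene. In the fla/che operon, which encodes the flagellar basal body and the chemotaxis machinery, 10 of 31 genes had a value on all 4 arrays (adjusted p = 0.0263 by the same exact test). Its means were led by cheD (0.71 ± 0.09), fliZ (0.44 ± 0.02), flhB (0.35 ± 0.02) and flhA (0.35 ± 0.05). Simulated unchanged genes that were listed on all 4 arrays averaged 0.73, so such means can arise without a change at the simulated spreads. Those spreads were not matched to the pair SDs of these genes, and 0.73 is no threshold for a single gene. The fla/che call was lost with the same number of listed genes per array (adjusted p = 0.538), on the forward arrays alone (adjusted p = 0.562) and without pair 1 (adjusted p = 0.176). It was also lost when list positions were shifted along the chromosome (adjusted p = 0.222). Camera with an estimated correlation, which kept no list, gave an adjusted p = 0.650. Over all genes 0 members of either list passed limma, and 0 did adjusted over the list alone.

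Genes for enzymes of the TCA cycle were also listed on all 4 arrays more often than other genes. Of 12 genes, 8 had a value on all 4 arrays (66.7%; Fisher's exact test, adjusted p = 0.000413). The call was lost on the forward arrays alone (Fisher's exact test, adjusted p = 0.346). Camera with an estimated correlation, which kept no list, gave an adjusted p = 0.650. The mean ratio of the malate dehydrogenase gene mdh was 2.84-fold, and on the log2 scale the citrate synthase gene citZ had a mean of 1.44 ± 0.44, the isocitrate dehydrogenase gene icd 1.38 ± 0.03 and the aconitase gene citB 1.10 ± 0.41. In this list 0 genes passed limma over all genes and 5 adjusted over the list alone, a count inflated because fitted values are never negative. Of the arginine list, 6 of 17 genes were listed on all 4 arrays, which missed the threshold (Fisher's exact test, adjusted p = 0.0691). All 6 were catabolic roc genes, led by rocG (3.31 ± 2.38), rocB (3.24 ± 0.89) and rocA (3.15 ± 0.30). Adjusted over the list alone 5 genes passed limma, a count inflated in the same way.

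Purine biosynthesis was the list with the largest share of genes without a value. Of its 21 genes, 19 (90.5%) had no value on any array, against 16.3% of all genes (Fisher's exact test, two-sided, adjusted p = 3.03e-12). Camera with an estimated correlation, which kept no list, gave an adjusted p = 0.650. The exceptions were guaC and ytiP (pbuO). Others with an excess of such genes were the translation factors and tRNA synthetases (17 of 31), wall teichoic, teichuronic and lipoteichoic acid synthesis (14 of 29), heat shock and protein quality control (11 of 19), PerR peroxide stress genes (8 of 12), the SigX regulon (9 of 16), pyrimidine biosynthesis (6 of 10), branched-chain amino acid biosynthesis (6 of 11), overflow and anaerobic metabolism (8 of 18) and peptidoglycan synthesis (12 of 37). Their adjusted p lay between 1.28e-05 for the translation list and 0.0461 for the peptidoglycan list (Fisher's exact test). With an estimated correlation 0 of these lists passed (camera), and on the swapped arrays alone 1 list passed, the purine list. Without pair 1 the adjusted p was 0.191 for the overflow list, 0.231 for the peptidoglycan list and 0.0726 for the pyrimidine list, and the overflow list was also lost without pair 2 (adjusted p = 0.136) and with equal listing (adjusted p = 0.127). With list positions shifted along the chromosome, the overflow, peptidoglycan, pyrimidine and branched-chain lists were lost (adjusted p = 0.0882, 0.109, 0.0974 and 0.0974). On the forward arrays alone 14 lists passed, but the pyrimidine and overflow lists were lost (Fisher's exact test, adjusted p = 0.0662 and 0.101). Camera lost the peptidoglycan list with a preset correlation (adjusted p = 0.0589). It lost the overflow list with ranks (adjusted p = 0.0886) and on separate arrays (adjusted p = 0.104). An absent value is no measured fall, since unrecorded spots are blank as well.

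**Figure D3:**
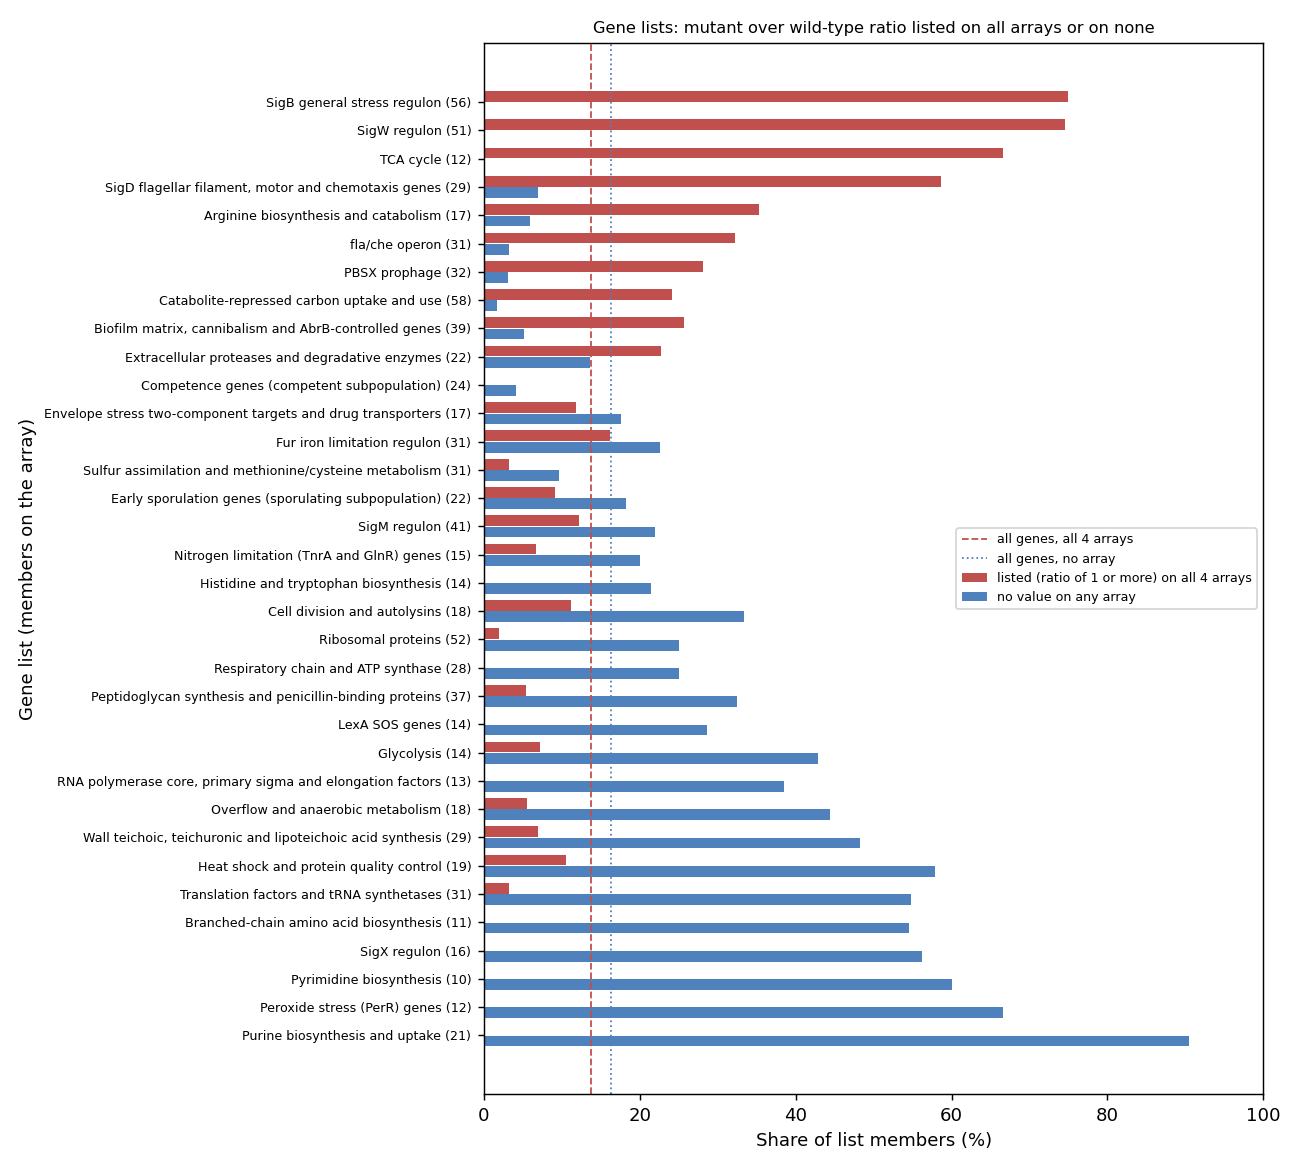
Share of members (x axis, percent) of each of the 34 gene lists (y axis, members on the array in brackets) with a value on all 4 arrays (red) or on none (blue); lines mark the shares over all genes, 13.8% and 16.3%. SigB and SigW reach 75% and 74.5% on all arrays, and the purine list reaches 90.5% on none.

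Among genes of the transcription machinery and the cell wall that were chosen for report whatever their values, rpoC, rpoB, sigM, sigX and murAA (the first enzyme of peptidoglycan synthesis) had no value on any array. A single-residue substitution does not remove the transcript, so rpoC does not check the labels. Single values were listed for rpoA (0.0013), sigA (0.04), abh (0.06), abrB (0.02) and pbpX (0.50), and ponA had 0.24 and 0.19, both in pair 2. Of the 41 SigM genes 5 had a value on all 4 arrays (Fisher's exact test, adjusted p = 1), led by ywaC (2.32 ± 0.14). Ribosomal protein genes were listed on all 4 arrays less often than other genes, 1 of 52 (adjusted p = 0.0277 by the exact test), namely rplI with 0.22 ± 0.05. This deficit lay in the forward orientation: 2 of the 52 were listed on both forward arrays and 30 on both swapped arrays. Catabolite-repressed carbon genes lacked any value less often than other genes, 1 of 58 (adjusted p = 0.00288 by the exact test). Neither the ribosomal nor the catabolite call was kept by camera with an estimated correlation, which kept no list. Of the 34 lists 17 passed in neither direction, among them the SigM and arginine lists, the Fur iron list (5 of 31 on all 4 arrays), with feuA at 2.56 ± 1.17, and the PBSX prophage (9 of 32), with xkdI at 1.08 ± 0.68.

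Correlations of listed log2 ratios, which run across genes and not across replicates, had a median Pearson r of 0.329 over the 6 pairs of arrays. Arrays of the same orientation gave r = 0.416 (forward) and 0.435 (swapped). The 2 arrays of the same RNA gave r = 0.296 in pair 1 and 0.361 in pair 2, lower than between arrays of the same orientation, a difference that was not tested.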

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

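All tests of explanations in this part were chosen after the result was seen.

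On 3 genes a single array lay far from the other 3, by the ratio of its gap to the whole range: yveP (epsF, biofilm matrix) at 0.853, xkdX (PBSX prophage) at 0.851 and degR at 0.860. In each the outlying value was a forward one, 7.34 in yveP, 6.99 in xkdX and 8.85 in degR. Chance marks about 1 in 20 of such sets, and 62 were examined. Control probes for E. coli and plant virus RNA, which the comparisons do not use, carried a value for 10 of 10 probes on the forward array of pair 1 and for 9 on that of pair 2 (up to 6.29 and 6.30), and for 0 and 2 on the swapped arrays (at 0 in the latter).

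Dye orientation set which genes were listed: 946 genes had a value on both forward arrays and no swapped array, and 235 the other way round. Of the forward values between 1.5 and 5 in the former, 62.6% were log2 of multiples of 0.5 (within rounding), against 5.73% in genes listed on all 4 arrays, a ratio of 10.9, so a floor in the Alexa Fluor 555 channel of weak spots is a candidate explanation for many of these values. Forward values above 5, among them those behind the 10 largest means, were not checked in this way. On swapped arrays that had not been turned to mutant over wild type, a difference between the RNA pairs would have the opposite sign from the forward arrays, while a dye effect shared by the pairs cancels. Instead the difference of pair 1 from pair 2 correlated positively between the orientations (Spearman 0.539 over 565 genes, bootstrap 95% range 0.459 to 0.613; 0.482 over 486 genes without the SigW and SigB lists), with the same sign in 388 genes. This argues against unturned arrays; dye effects that differed between the pairs were not tested. No biological explanation was tested, since orientation is not a property of the strains.

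Values of the SigW and SigB lists stood apart between the RNA pairs. SigW members were higher in pair 1 than in pair 2 by a median of 0.98 log2 units (31 of 38 members), and the SigB median difference was -0.38 (38 of 42 members below 0), which argues against a shift of all ratios in one pair. Dye orientation is argued against as well, since the SigW difference was 0.93 on both the swapped and the forward arrays (41 of 44 and 35 of 43 members above 0). A difference between the cultures or RNA preparations may remain; with 2 pairs it stays untested.

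No value on any array was found for 670 genes, where independent arrays would give 273. Whether a gene was listed correlated between arrays of the same orientation (0.493 forward, 0.494 swapped) and hardly between others (0.0212 to 0.0996). The forward arrays shared 1900 listed genes and the swapped arrays 1053. With listing taken as independent between orientations, blanks shared within an orientation can therefore account for most of the excess. Spots too weak to record should be commonest in genes usually silent during growth. Such genes (competence, early sporulation, PBSX and biofilm lists) lacked any value in 6.84% of cases (8 of 117), and abundant transcripts (ribosome, translation, glycolysis and RNA polymerase lists) in 37.3% (41 of 110; Fisher's exact test, two-sided, p = 1.53e-08). Failed spots at random are argued against by the chromosome: 34.4% of the neighbours of such genes lacked a value too, against 15.7% of all placed genes. Both forward arrays listed 28 of 39 biofilm, 24 of 32 PBSX, 11 of 22 sporulation and 4 of 24 competence genes. For the abundant lists this was 2 of 52 ribosomal, 1 of 31 translation, 1 of 14 glycolysis and 0 of 13 RNA polymerase genes. A floor that gives weak spots a forward value would thus make blanks rarer in silent genes. The shares cannot separate a lower level in the mutant from abundance and orientation. That level stays open, as does the authors' filtering, which is not described.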

How the results depend on the processing

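The settings with equal listing, array names alone, shifted gene order, 1 orientation for lists, rank product and adjustment over complete genes were chosen after seeing the data. Of the alternatives for the gene-wise count of 0, 2 moved it: 72 genes with the RNA pair as a random block and 46 with no block. The latter counts arrays of the same RNA as separate samples; the block did not make the test stricter, since the estimated correlation within a pair was -0.0314. Without replicate 1 or 2 no residual degrees of freedom remain, so that count was not run, nor were median centring and a pseudocount. The 87 genes at least 2-fold on all arrays became 184 at 1.5-fold, 24 at 3-fold, 41 with equal listing and 216 to 222 without a replicate. Lists with more members on all arrays numbered 5, and 0 with an estimated correlation, 8 with camera on separate arrays and 4 to 9 without a replicate. With an estimated correlation the adjusted p was 0.654 for SigB, 0.710 for SigW and 0.650 for SigD, TCA and fla/che. That correlation is estimated from 2 pair means, so the setting could hardly keep any list. Fry gave 3 lists, with 0.0893 for SigB, 0.0873 for SigW and 0.0858 for SigD, but it compares a list with no change, not with other genes, and blanks at 0 fix its direction, so it says nothing about these calls. On the forward arrays TCA gave 0.346 and fla/che 0.562; fla/che also gave 0.538 with equal listing, 0.222 with the shifted gene order, and 0.0238 to 0.176 without a replicate. The cause of these losses was not tested. Lists with more genes without any value numbered 10, and 1 on the swapped arrays, 0 with an estimated correlation and 6 with the shifted gene order; fry was left out for them for the same reason. Of the 59 named genes with a mean, 32 moved by more than the SD of the pairs with 1 orientation alone and 13 of 41 still listed did so with equal listing. Signal over background is unknown here, so weak spots could not be set apart.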

Other observations

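Of the 87 genes at least 2-fold on all arrays, 48 lay outside every list. They and the genes below were named after their values were seen. The galactan genes yvfO, lacA and yvfM had means of 2.73 ± 0.29, 2.17 ± 0.60 and 2.32 ± 0.28 (SD, n = 2), the glucosamine genes gamP and gamA 1.98 ± 0.15 and 1.78 ± 0.24, malA (a maltose 6-phosphate glucosidase) 1.37 ± 0.03, malS (a malic enzyme) 1.70 ± 0.03, and the dicarboxylate transporter gene dctP 2.26 ± 0.70. The acetoin utilisation genes acuB and acuC stood at 2.04 ± 0.28 and 1.77 ± 0.18, and ald (alanine dehydrogenase) at 1.51 ± 0.19. The oxalate decarboxylase gene oxdC had 2.31 ± 0.59. Of the SigM list, yjbD (spx, a regulator of the thiol stress response) had 1.80 ± 0.28. None passed limma. No enrichment was tested for these genes, and in the fixed list of catabolite-repressed carbon genes 14 of 58 were listed on all arrays, which missed the threshold (Fisher's exact test, adjusted p = 0.0942), and 0 were at least 2-fold on all of them.

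Genes at least 2-fold on all arrays lay next to each other: of 65 placed on the gene order, 25 had a neighbour in the set, against a mean of 2.63 and a maximum of 15 in 10000 random sets (permutation p = 0.0001, the smallest these can give). The 11 runs included feuC, feuB and feuA, lytC, lytB and lytA, yxiS, katE and citH, and the pairs rocE and rocD, racX and pbpE, and ydbS and ydbT. Random sets do not keep operons together, so this p describes clustering and no regulator.

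Of 31 iron acquisition genes of the Fur list, 19 had a value on both arrays of pair 1 and 5 on both arrays of pair 2; over all 4106 genes these counts were 970 and 997. The flavodoxin gene ykuP stood at 2.25 and 2.47 in pair 1 and the bacillibactin gene dhbE at 1.08 and 2.15, both without a value in pair 2, while feuA was at 2.97 and 3.82 in pair 1 and 1.36 and 2.11 in pair 2. Each pair is 1 replicate, and the difference between them was not tested.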
